A study of Mus musculus and Homo sapiens with 19 samples.

How the data were processed

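The series held 19 libraries of cultured cells. These were 3 shSCR and 3 shPHGDH 4T1 libraries, 3 control and 3 libraries labelled PHGDH-overexpressing of MDA-MB-231, and 7 co-culture libraries. The co-culture set had 1 library each of 4T1, EMT6.5 and Bend3 alone, of 4T1 and Bend3 sorted from their co-culture, and of EMT6.5 and Bend3 sorted from theirs. Per the labels, RNA was extracted with TRIzol, tumour and endothelial cells of co-cultures were separated by FACS before extraction, and 1 µg of total RNA went into stranded mRNA libraries that were sequenced as 50 bp single-end reads.

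The deposited tables held raw gene counts, which the authors made, per the submitters' processing notes, with Trim Galore 0.5.0, HISAT2 2.1.0 and HTSeq (version not given) on GRCm38 for mouse. The human build, the annotation and the counting settings were not given in the sources used here. The knockdown table had 1 entry per gene symbol, 24421 in all, and no summary lines, unlike the other tables, so which counting tool made it is not certain. It held 16 library columns; 6 matched the labels of the knockdown samples, and the other 10 were not used here. The MDA-MB-231 table named its controls SCR, which was read as the control label, and held 57992 human Ensembl genes. The 7 co-culture tables held mouse Ensembl genes and 5 summary lines each. No table held molecular identifiers, so intervals and floors cover counting error only.

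Assigned counts, in M, were 14.4, 17.0 and 19.0 for shSCR 1 to 3, 16.2, 12.7 and 20.5 for shPHGDH 1 to 3, 23.8, 19.5 and 19.7 for the MDA-MB-231 controls and 19.7, 23.6 and 19.6 for the libraries labelled PHGDH-overexpressing. They were 4.30 for 4T1 alone, 7.67 for EMT6.5 alone, 4.78 for Bend3 alone, 4.27 for 4T1 with Bend3, 5.87 for Bend3 with 4T1, 4.69 for EMT6.5 with Bend3 and 5.75 for Bend3 with EMT6.5. In the co-culture libraries gene counts made up 34.0% to 39.8% of all entries, gene counts and summary lines together. Entries aligned to several places made up 48.2% to 55.3%, against 3.54% to 3.70% in MDA-MB-231. Entries in no gene made up 9.27% to 11.6% in the co-culture set and 3.42% to 4.50% in MDA-MB-231. Whether the summary lines count reads or alignments was not given, so these may not be shares of reads. The 10 most abundant genes took 4.07% to 5.41% of counts in the knockdown, 3.88% to 5.10% in MDA-MB-231 and 8.47% to 15.9% in co-culture. Chi-square over degrees of freedom between replicates was 1.63 to 20.8 in the knockdown and 2.99 to 8.35 in MDA-MB-231, so no pair of libraries was a copy; shPHGDH replicate 1 stood apart from replicates 2 and 3 (14.9 and 20.8, against 1.76 between those).

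The knockdown and the MDA-MB-231 experiment were each fitted with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default filter for low counts and the quasi-likelihood F-test, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. No block was used, since replicate numbers are not said to pair cultures. With 3 against 3 libraries 10% of genes have groups that do not overlap by chance in any direction. Gene lists, 28 in all, were written with the settings before the data were examined, and a list was tested when it had at least 5 tested members. Lists were tested with camera on the edgeR dispersions (limma 3.58.1, preset correlation 0.01, adjusted over the lists), and again with an estimated correlation. Fry was run as well; it asks whether the genes of a list move on balance one way and does not compare them with other genes. Genes called in the knockdown were matched by symbol to MDA-MB-231 and tested there with camera.

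Co-culture ratios came from TMM log2 CPM with a prior count of 2 for genes with a mean of at least 5 CPM, and a gene was counted when it changed at least 2-fold in both libraries. Ratios printed for a gene are CPM ratios with 95% exact counting intervals. Each list's median ratio was placed among 10000 random lists of the same size matched on expression in 20 bins. The same was done, after seeing the data, for the replicates of each group in the replicated experiments, 12 comparisons of 2 replicates with the third. The share of partner RNA was estimated from genes with at least 50 CPM in the partner and at most 0.5 CPM in the host alone. The overlap expected in Bend3 from the shared control was simulated 100 times with the dispersions of the shSCR libraries. What both lines or both partners share was also fitted with edgeR, which leaves 1 residual degree of freedom; in Bend3 the lone monoculture is assumed to vary like the co-cultures. Chromosome positions came from GENCODE vM21 on GRCm38, which placed 96.5% of the knockdown genes, and windows of 50 neighbouring genes were compared with 1000 shuffles of the gene order.

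Named genes followed a fixed rule. The 22 core genes are given in each comparison. In the replicated experiments the 10 largest rises and 10 largest falls were named among called genes with a mean of at least 10 CPM and no overlap between groups, with up to 3 called members, by smallest p, of each list that was called or had at least 3 called members. In co-culture the 10 largest mean rises and falls among genes 2-fold changed in both with a mean of at least 20 CPM were named, rises only beyond the partner's share, with up to 3 members of each list in the lowest or highest 2.5% of random lists in both. Predicted genes, pseudogenes, histone and mitochondrial genes were left out of the ranked picks. A few genes that the rule names are not reported here. Pdgfra, Col6a2, CSF1R and LAPTM5 were named outside this rule, after their values were seen. A fold against a group at 0 counts was taken against a floor of 3 counts over the group.

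The fits were tested on simulated data with 50 genes changed at each size. In the knockdown, over 11507 genes, edgeR recovered 80%, 100%, 98% and 98% of genes with log2 changes of 0.263, 0.585, 1 and 2 with 10 false calls. In MDA-MB-231, over 17702 genes, it recovered 26%, 96%, 100% and 100% with 19 false calls. Camera called 0 and 1 lists where none was changed and recovered a glycolysis list raised by 0.3 in both. The simulated genes were drawn independently, so this does not measure false list calls among correlated genes. A list raised by 0.5 in Bend3 with 4T1 came out at the 100 percentile, with 1 of 24 other lists in the lowest or highest 2.5%. A planted partner share of 2% was estimated at 1.96%, and a shift of chromosome 14 by 0.5 raised the window statistic to 1.86 times the highest shuffle, from 0.902 with none planted.

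The alternatives were DESeq2 1.42.0, limma voom, RLE and library totals as scaling, no filter and a filter at 5 CPM, an adjusted p under 0.01, a 2-fold limit, lane as a covariate, lane 6 only, a replicate block, each replicate left out in turn, prior counts of 0.5 and 5, co-culture floors of 1 and 20 CPM, a 4-fold limit and stricter choices for the partner share. A count without the chromosomes whose median was shifted by 0.2 or more was added after seeing the data.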

Results

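The series compared breast cancer cells with different PHGDH levels. PHGDH encodes the enzyme that starts serine synthesis from a glycolytic intermediate. The cells were 4T1 and EMT6.5, both mouse mammary tumour lines, and MDA-MB-231, a human breast cancer line. Bend3 is a mouse endothelial line. Values in parentheses after a gene are log2 fold changes unless another unit is given, and in the replicated experiments "rose" and "fell" are used for genes called at an adjusted p under 0.05 by edgeR. In co-culture a rise or a fall is a ratio without a test.

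The shRNA lowered its target. Phgdh, on GRCm38 chromosome 3 from 98313170 to 98339990, was at 167, 173 and 163 CPM (counts scaled to a library of 1 M) in the 3 scramble-shRNA (shSCR) libraries and at 20.7, 20.21 and 21.7 in the 3 PHGDH-shRNA (shPHGDH) libraries. The means were 168 ± 4.58 and 20.9 ± 0.746 CPM (SD, n = 3 each), and 8549 and 1023 counts were summed over the groups. Phgdh was 7.99-fold lower in shPHGDH (log2 -2.999, SE 0.04, edgeR adjusted p = 5.16e-28). Its next enzymes moved the other way and by far less: Psat1, the transaminase of the pathway, rose (0.39) and so did the phosphatase Psph (0.23). Of the one-carbon enzymes, Shmt2 (0.10) and Mthfd2 (0.24) rose and Shmt1 fell (-0.11). The Shmt1 call was lost with DESeq2, with lane in the model, without shSCR replicate 2 (adjusted p = 0.105, edgeR) and without shPHGDH replicate 3 (0.191). The Shmt2 call was lost with library totals as the only scaling.

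**Figure D1:**
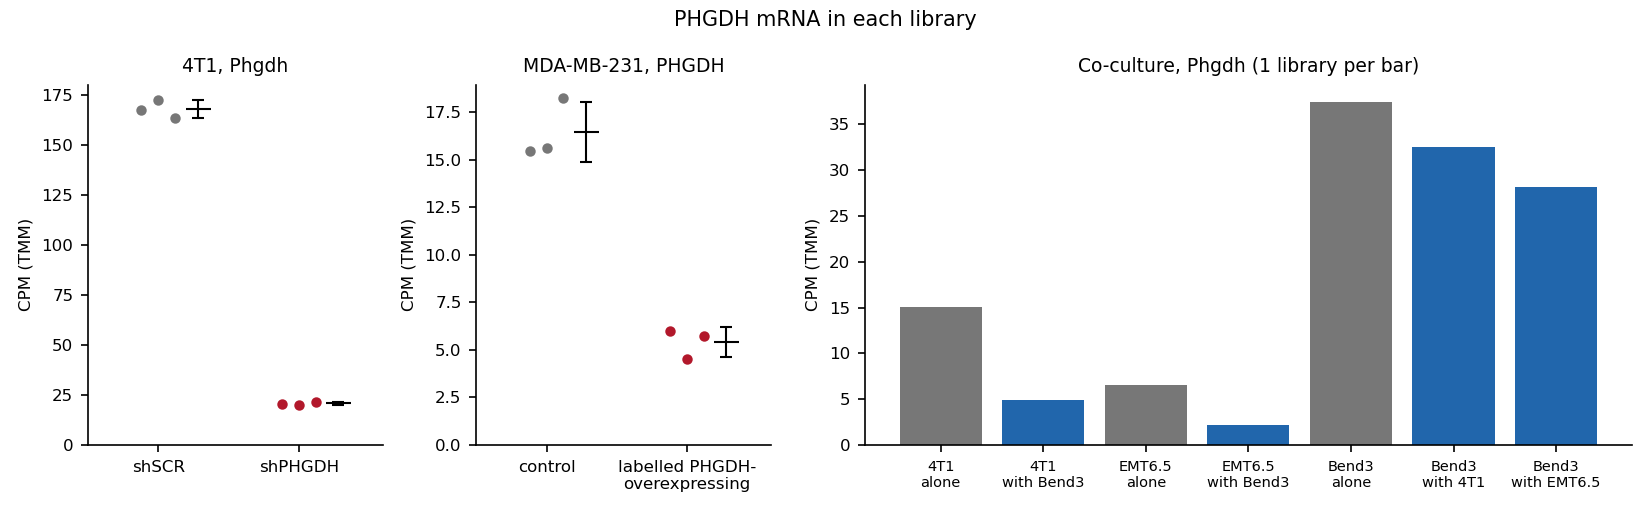
PHGDH in CPM after TMM scaling in each library, with points for libraries and bars for the mean ± SD (n = 3) in 4T1 and MDA-MB-231, and 1 library per bar in the co-cultures. The shPHGDH libraries sit between 20.21 and 21.7 CPM against 163 to 173 in shSCR, and the MDA-MB-231 libraries labelled PHGDH-overexpressing sit between 4.53 and 5.99 CPM against 15.5 to 18.3 in their controls.

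The knockdown libraries differed from shSCR in matrix, integrin and epithelial genes, whose lists were called by camera with its preset correlation but not with an estimated one (adjusted p of 0.076, 0.076 and 0.137). Proteases that break down matrix rose: Mmp3 (4.36, from 1.96 to 40.5 CPM), Mmp9 (2.45, from 41.4 to 226 CPM) and the urokinase Plau (2.21, from 50.1 to 233 CPM). The secreted protein Spp1, also called osteopontin, rose (1.498). The intermediate filament Vim (1.07) and the motility protein S100a4 (2.57) rose, while the cell adhesion molecule Cdh1 fell (-0.60), as did the basal keratin Krt17 (-3.27), the keratin Krt14 (-1.02), the tight junction protein Cldn7 (-1.45) and the epithelial splicing factor Esrp1 (-1.45). Integrin subunits that bind collagen, laminin or fibronectin rose: Itga2 (1.17), Itga6 (0.76) and Itga5 (0.92). Itgb3 rose as well (1.74), but from 1.98 to 6.52 CPM. Itgav rose (0.12) and Itgb1 fell (-0.11). The gene medians of several chromosomes were shifted between the arms, and Plau lies on chromosome 14 (median 0.51), Itga2 on chromosome 13 (0.25), Itga5 on chromosome 15 (0.28), Cdh1 and Itgb1 on chromosome 8 (-0.25) and Esrp1 on chromosome 4 (-0.22). Vim lies in a window of neighbouring genes on chromosome 2 with a median of 0.42.

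Of 11568 genes tested in the knockdown, 3484 were higher and 3421 lower in shPHGDH, 59.7% of those tested, and 333 and 220 of them changed 2-fold or more. With library totals in place of TMM, 3027 were higher and 4023 lower, so the higher share of calls was 42.9% against 50.5%. The biological coefficient of variation was 3.23%, so small changes were called: in simulated libraries of this depth and spread, 80% of genes with a log2 change of 0.263 and 100% with 0.585 were recovered. The p-values measure the spread between these libraries, since the labels do not say that the replicates were separate cultures. The libraries shSCR 1 and 2 were run on lane 5 and the other 4 on lane 6. With lane in the model 3008 genes were higher and 2791 lower. Of the genes called without lane, 5529 were called in the same direction with lane. Among all genes called without lane, 9 changed sign with lane in the model, whether called there or not. Within lane 6, which holds 1 shSCR library, 3104 were higher and 2834 lower; the spread of that fit comes from the shPHGDH libraries alone, and the lone shSCR library is assumed to vary like them.

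The matrix remodelling list (20 tested genes) rose, with 14 members higher, 3 lower and 3 not called, a median of 0.66 and a camera adjusted p of 6.59e-19; with the correlation between genes estimated from the data in place of the preset it was 0.076. The integrin list had 12 higher, 3 lower and 2 not called (median 0.80, adjusted p of 4.27e-06, estimated correlation 0.076). Of 17 mesenchymal genes, 10 rose and 5 fell, among them the matrix protein Thbs1 (-1.27), with a median of 0.50 and an adjusted p of 0.000627 (estimated correlation 0.197); the call was lost with lane in the model (0.093), without shSCR replicate 2 (0.0881) and without shSCR replicate 3 (0.0511). Of 24 epithelial genes, 14 fell and 6 rose, with a median of -0.27 and an adjusted p of 6.9e-09 (estimated correlation 0.137). None of the 11 lists called in the knockdown held its call with an estimated correlation. The estimate lay below the preset 0.01 for integrins (-0.03), glycolysis (-0.02), hypoxia (0.007), inflammatory (-0.02), antigen presentation (-0.04) and endothelial genes (-0.19). For these lists a higher correlation between genes is not what lost the call. Counts of members adjusted over the list alone were the same as over all genes for every list of the knockdown except the ATF4, inflammatory and heat shock lists.

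Genes of amino acid stress and lipid synthesis were also higher after knockdown. Atf4, the factor that drives the response to missing amino acids, rose (0.56; chromosome 15, median 0.28), and so did Cth, which makes cysteine (1.49). The lipoprotein receptor Vldlr had 0 counts in shSCR and 327 in shPHGDH, at least 114-fold higher against a floor of 3 counts over the group. Of 31 genes on the ATF4 list 18 rose, 5 fell and 8 were not called; adjusted over the list alone, 18 rose and 6 fell. The list median was 0.17, with Vldlr at its bound as well, and the adjusted p 0.000627 (estimated correlation 0.345). Of 22 cholesterol genes 17 rose, 1 fell and 4 were not called (median 0.27, adjusted p of 4.27e-06, estimated correlation 0.197). Examples were the synthase Hmgcs1 (0.83; chromosome 13, median 0.25) and the epoxidase Sqle (0.61; chromosome 15). Of 18 glycolysis genes 12 rose and 0 fell (median 0.20, adjusted p of 0.025, estimated correlation 0.197), among them Tpi1 (0.30) and Pkm (0.22); of the phosphofructokinases Pfkp (0.72; chromosome 13, median 0.25) and Pfkm (0.53; chromosome 15, median 0.28) rose and Pfkl was not called (-0.03, adjusted p = 0.256). Pfkl was called lower with library totals and without shSCR replicate 3 (adjusted p = 0.0385, edgeR).

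Hypoxia, inflammatory, antigen presentation and endothelial genes were called as lists with members on both sides. Of 16 hypoxia genes 7 rose and 1 fell: Ero1l (1.04; chromosome 14, median 0.51) and Egln3 (1.21) rose, and the carbonic anhydrase Car9 fell (-2.30; chromosome 4, median -0.22), with a list median of 0.04. Of 17 inflammatory genes 8 rose and 4 fell (5 adjusted over the list alone), with a median of 0.18. The cytokine Il1a (4.998, from 0.488 to 16.1 CPM) and Tnfaip2 (2.11, in a chromosome 12 window with median 0.42) were higher and the inhibitor Tnfaip3 was lower (-0.45). Antigen presentation was lower (median -0.49): of 12 genes 2 rose and 8 fell, with the immunoproteasome subunit Psmb8 (-0.87) and the regulator Nlrc5 (-0.90; chromosome 8, median -0.25) lower and the peptidase Erap1 higher (0.59; chromosome 13, median 0.25). Of 6 endothelial markers 5 rose and 1 fell (median 0.64), with Eng (0.52) and Flt1 (0.76) higher and S1pr1 (2.94) higher from 0.185 to 1.53 CPM. All 4 lists had an adjusted p of 0.0389, and 0.197 with the estimated correlation; the inflammatory call was lost with lane in the model (0.303) and without shSCR replicate 2 (0.264) or 3 (0.258), and the endothelial call without shPHGDH replicate 2 (0.0524).

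The serine and one-carbon list itself was not called after knockdown (adjusted p = 0.679, camera on the edgeR dispersions): of 23 genes 11 rose, among them the folate carrier Slc25a32 (0.51; chromosome 15, median 0.28), 6 fell and 6 were not called. Its median was 0.05, its mean -0.06 and its tested direction down. The hexosamine and sialic acid list, which feeds protein glycosylation, was not called either (8 rose, 7 fell, 8 not called, median 0.02, adjusted p of 0.855). Among its genes Cmas (0.15), St3gal4 (0.34) and the sialyltransferase St6gal1 (0.75) rose, as did St3gal1 (0.22; chromosome 15, median 0.28) and Gnpnat1 (0.60; chromosome 14, median 0.51). Nans (-0.21) and Gne (-0.29) fell, both on chromosome 4 (median -0.22), and Gfpt1 was not called (-0.01, adjusted p = 0.751). Gfpt2 had 0 to 2 counts per library and was not tested.

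Proliferation lists were not called in the knockdown. Of 23 G2/M genes 9 rose, 5 fell and 9 were not called (median -0.01, mean 0.01, direction up, adjusted p of 0.981), with Ccna2 (0.18) and Ccnb2 (0.26) higher and Nusap1 lower (-0.36). The proliferation marker Mki67 was not called (-0.02, adjusted p = 0.693), but was called lower with lane in the model and without shSCR replicate 2 (adjusted p = 0.0106, edgeR). Of 22 S phase genes 11 rose, 8 fell and 3 were not called (median 0.07, mean -0.00, direction up, 0.956), with Rrm2 (0.30) and Mcm4 (0.28) higher and Gins2 lower (-0.65; chromosome 8, median -0.25). Of 16 nucleotide synthesis genes 7 rose, 6 fell and 3 were not called (median 0.06, 0.855), with Umps (0.33) and Ppat (0.25) higher and Ctps lower (-0.23; chromosome 4, median -0.22).

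Of the remaining lists in the knockdown, the interferon response had 8 higher, 6 lower and 9 not called (median 0.07, mean 0.16, direction down, adjusted p of 0.598), with Ddx58 (-0.60; chromosome 4, median -0.22), Oasl1 (-1.14) and Ifit2 (-0.70) lower. Notch and angiogenesis genes had 10 higher, 3 lower and 2 not called (median 0.25, 0.531), with Nrp2 higher (0.35) and Notch1 (-0.69) and Nrp1 (-0.78; chromosome 8, median -0.25) lower. Immediate early genes had 9 higher, 2 lower and 6 not called (median 0.15, 0.515): Fosl1 (0.70) and Ier5 (0.28) rose and Junb fell (-0.29; chromosome 8). Heat shock genes had 3 higher, 3 lower and 3 not called, or 4 higher adjusted over the list alone (median 0.09, 0.855). Hsp90aa1 (0.43, in a chromosome 12 window with median 0.42) and Hspd1 (0.12) were higher and Bag3 (-0.19) lower. Of 14 p53 targets 2 rose, 7 fell and 5 were not called (median -0.11, mean 0.01, direction down, 0.708); the cell cycle inhibitor Cdkn1a (1.48) and Tnfrsf10b (0.93; chromosome 14, median 0.51) rose and Perp fell (-0.47).

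Mitochondrial and stress lists were mixed as well after knockdown. Of 26 respiratory chain genes 8 rose, 7 fell and 11 were not called (median -0.01, mean 0.06, direction up, adjusted p of 0.531). Atp5c1 (0.40, in a chromosome 2 window with median 0.42), Sdha (0.46, chromosome 13, median 0.25) and Cox6c (0.52, chromosome 15, median 0.28) were higher. Of 16 TCA cycle genes 6 rose, 7 fell and 3 were not called (median 0.03, mean -0.04, direction down, 0.855), with Cs (-0.28) and Mdh1 (-0.44) lower and Sucla2 higher (0.41; chromosome 14, median 0.51). Of 18 unfolded protein genes 8 rose, 3 fell and 7 were not called (median 0.08, 0.515), with Hspa5 (0.20), Hyou1 (0.20) and Dnajc3 (0.63; chromosome 14) higher. Of 17 YAP and TGF-beta targets 6 rose, 7 fell and 4 were not called (median -0.01, 0.806), with Ctgf lower (-0.67) and Lats2 (0.90) and Ajuba (0.44), both on chromosome 14, higher. Of 15 NRF2 targets 4 rose, 7 fell and 4 were not called (median -0.06, mean 0.09, direction up, 0.981), with Abcc1 (0.43), Tkt (0.46; chromosome 14) and Nqo1 (2.00; chromosome 8, median -0.25) higher.

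The fibroblast and leukocyte lists had too few tested genes for camera in the knockdown. Of the 3 fibroblast markers Pdgfra rose (0.53), the collagen Col6a1 fell (-1.52) and Col6a2 was not called. Of the 4 leukocyte markers 3 rose and 1 was not called. These were Cd68 (1.06), Lyz2 (1.49) and Cd14 (0.26), at 3.93, 1.16 and 7.93 CPM in shPHGDH. The Lyz2 call was lost without shSCR replicate 1 or 2 or shPHGDH replicate 1 (adjusted p = 0.0909, 0.0691 and 0.0541, edgeR), with DESeq2 (adjusted p = 0.411) and with lane in the model, where its log2 fold change was 0.16 (adjusted p = 0.773, edgeR). The Cd14 call was lost when any library other than shSCR replicate 2 was left out, with adjusted p from 0.0637 to 0.16 by edgeR, and also with DESeq2 (0.198), library totals (0.0891) and lane in the model (0.153).

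Other large changes after knockdown were not on the lists. The ubiquitin-binding gene Ubqln2, on chromosome X, had 0 counts in shSCR and 1560 in shPHGDH, at least 544-fold higher. The growth factor Bmp7 (4.55), the actin bundler Lcp1 (2.64; chromosome 14, median 0.51), the receptor Lrp1 (2.62) and the neuronal pentraxin Nptx1 (2.502) rose. The sodium channel Scn3a (-2.64), the non-coding RNA Lincenc1 (-2.43), the exchange factor Arhgef19 (-2.23; chromosome 4, median -0.22), the desmosomal Dsc2 (-2.09), the receptor Adgrf5 (-1.75) and the myosin Myh14 (-1.49) fell.

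**Figure D2:**
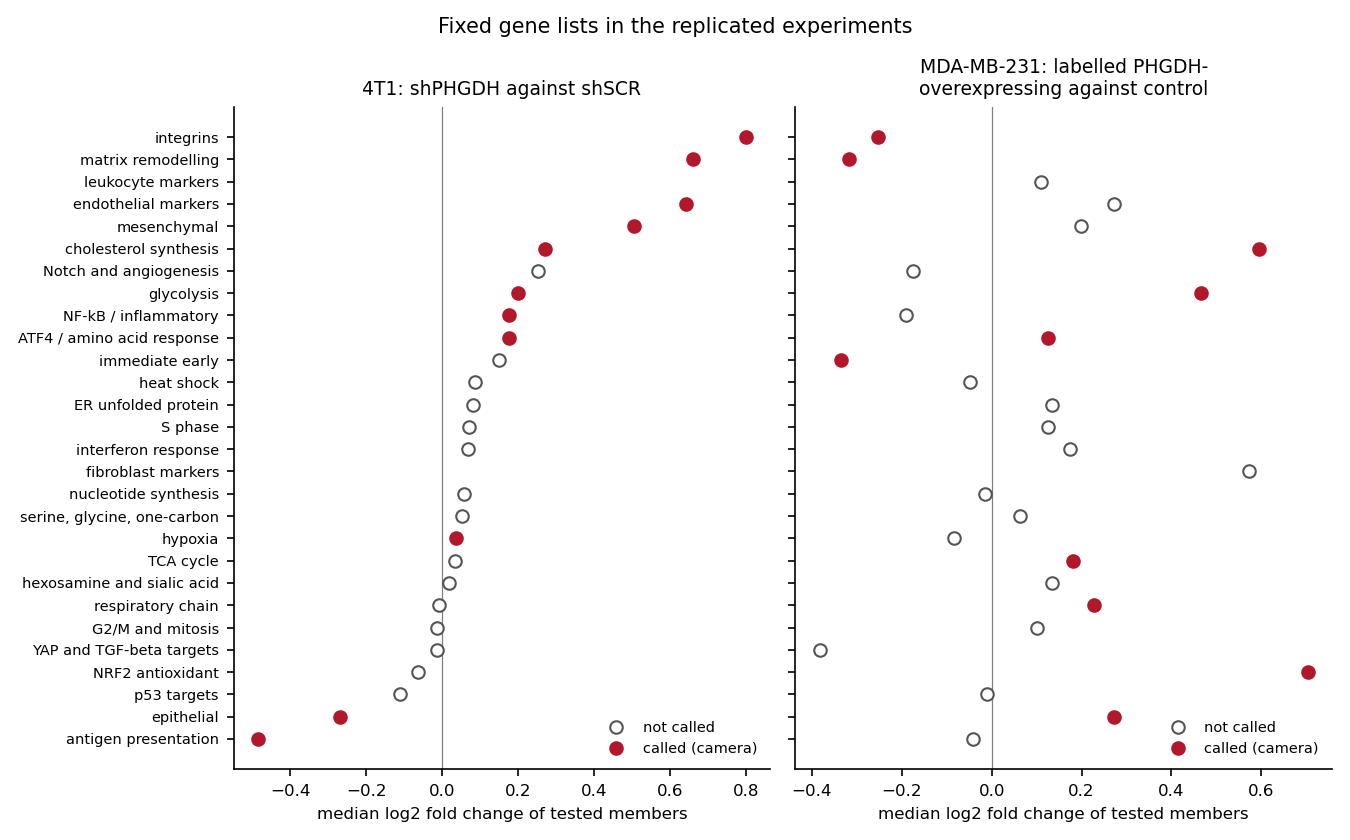
Median log2 fold change of the tested members of each gene list, in shPHGDH against shSCR 4T1 libraries and in MDA-MB-231 libraries labelled PHGDH-overexpressing against control (3 against 3 libraries each), with filled points for lists with a camera adjusted p under 0.05. Integrins lie at 0.80 and -0.25, matrix remodelling at 0.66 and -0.32, and cholesterol synthesis at 0.27 and 0.59.

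Whole chromosomes moved together between the knockdown arms. Chromosome 14 had a median log2 fold change of 0.51 over 372 genes, of which 315 were higher and 3 lower. Chromosomes 15 (0.28) and 13 (0.25) were shifted up, and chromosomes 8 (-0.25, with 52 of 625 genes higher and 435 lower) and 4 (-0.22) down. The SD of the medians of 211 windows of 50 neighbouring genes was 0.173, against at most 0.0556 in 1000 shuffles of the gene order. On these 5 chromosomes 75.1% of 2559 genes were called. Elsewhere it was 55.3% of 9009 genes, with 2507 higher and 2477 lower. Those chromosomes were not free of shifts either: chromosome 9 had 325 higher and 68 lower, chromosome 3 258 and 89, and chromosome 10 72 and 269. Single windows there were shifted too. On chromosome 2 the window from 3114224 to 18676231 had a median of 0.42 and holds Vim and Atp5c1. On chromosome 12 the window from 99693045 to 119469987 had a median of 0.42 and holds Tnfaip2 and Hsp90aa1. Changes of 2-fold or more were called for 143 of the 2559 genes on the 5 shifted chromosomes and for 410 of the 9009 elsewhere. This was a somewhat larger share on the shifted chromosomes. Of the 11 lists, 10 kept their call in the genes elsewhere; glycolysis lost it (adjusted p of 0.0926) and the Notch list gained one (0.0332). This comparison was chosen after seeing the data. Counted apart from this, 26 genes were at 3 counts or fewer over one arm and at 1 CPM or more in the other, 25 of them in shPHGDH only. Ubqln2 and Vldlr were among the 26. These genes lay on 14 chromosomes, and 8 of the 26 were on the 5 shifted ones.

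**Figure D3:**
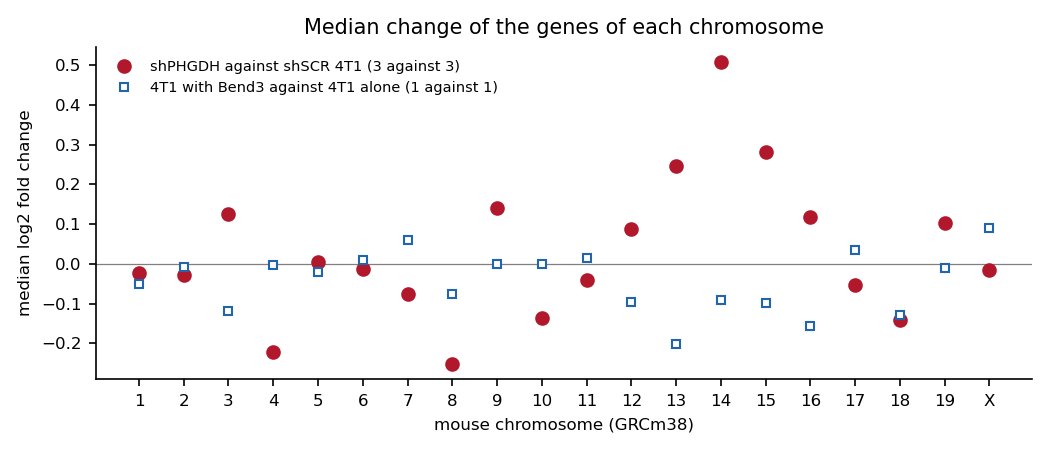
Median log2 ratio of the genes of each mouse chromosome, for shPHGDH against shSCR 4T1 (red, 3 against 3 libraries) and for 4T1 with Bend3 against 4T1 alone (open blue squares, 1 library each). In the knockdown chromosome 14 lies at 0.51 and chromosome 8 at -0.25.

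In MDA-MB-231, PHGDH mRNA ran against the label. PHGDH (ENSG00000092621) was at 15.5, 15.7 and 18.3 CPM in the controls and at 5.99, 4.53 and 5.71 in the libraries labelled PHGDH-overexpressing. The means were 16.5 ± 1.57 and 5.41 ± 0.773 CPM (SD, n = 3 each), from 1054 and 330 counts, a level 3.06-fold lower (log2 -1.61, SE 0.12, edgeR adjusted p = 5.76e-10). The directions given for this experiment follow the labels, so "rose" means higher in the libraries labelled PHGDH-overexpressing, which held less PHGDH mRNA. The one-carbon enzymes SHMT1 (0.87) and SHMT2 (0.59) rose, and PSPH (0.14, adjusted p = 0.149) and MTHFD2 (0.02, adjusted p = 0.869) were not called. PSAT1 rose (0.18), a call lost with library totals, without control replicate 1 (adjusted p = 0.132, edgeR) and without replicate 1 of the libraries labelled PHGDH-overexpressing (0.0668). Of 24 serine and one-carbon genes 7 rose, 7 fell and 10 were not called (median 0.06, mean -0.05, direction up, 0.787).

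Lipid, antioxidant and energy genes were higher in the libraries labelled PHGDH-overexpressing, which had less PHGDH mRNA. Whether the PHGDH level caused this was not tested. All 23 cholesterol synthesis genes rose (median 0.59, adjusted p of 8.62e-20, estimated correlation 0.139), with the sterol sensor INSIG1 (1.62, from 82.7 to 254 CPM), EBP (1.39) and DHCR7 (0.99) among them. All 15 NRF2 targets rose (median 0.70, adjusted p of 1.73e-17, estimated correlation 0.149), with the ferritin FTH1 (1.31) and the quinone reductase NQO1 (0.93). Of 20 glycolysis genes 16 rose, 1 fell and 3 were not called (median 0.47, adjusted p of 5.13e-08, estimated correlation 0.343), with PKM (0.93), PFKFB4 (0.96), GAPDH (0.63), PFKM (0.53), PFKP (0.47) and PFKL (0.30) higher. Of 26 respiratory chain genes 18 rose, 3 fell and 5 were not called, or 20 higher adjusted over the list alone (median 0.23, adjusted p of 0.00476, estimated correlation 0.428), with COX5A (0.88), NDUFA9 (0.52) and ATP5B (0.46). Of 16 TCA cycle genes 8 rose and 2 fell, or 10 higher adjusted over the list alone (median 0.18, adjusted p of 0.0247, estimated correlation 0.347), with CS (0.69), IDH3A (0.65) and MDH2 (0.56).

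Matrix and integrin genes were lower in the same libraries, as lists only with the preset correlation. The plasminogen activator PLAT (-2.18) and the protease ADAMTS1 (-3.05) fell and the inhibitor TIMP1 rose (0.82); of 18 matrix genes 6 rose, 10 fell and 2 were not called (median -0.32, adjusted p of 0.0002, estimated correlation 0.343). ITGAV (-0.53), ITGB1 (-0.46) and ITGA6 (-0.97) fell and ITGB4 rose (0.57). Of 13 integrins 2 rose, or 3 adjusted over the list alone, and 9 fell (median -0.25, adjusted p of 0.0231, estimated correlation 0.44), a call lost without replicate 2 of the libraries labelled PHGDH-overexpressing (0.0507). ITGB3 was not called (0.38, adjusted p = 0.0612), but was called higher without control replicate 3 (adjusted p = 0.0383, edgeR). Keratins KRT7 (1.23) and KRT8 (0.61) and the claudin CLDN4 (0.88) rose; of 16 epithelial genes 8 rose, 4 fell and 4 were not called (median 0.27, adjusted p of 0.0113, estimated correlation 0.343). CDH1 had 1 to 3 counts per library and was not tested. VIM rose (0.37), as did TGFBI (1.51) and S100A4 (1.07), and LOX fell (-0.78); of 19 mesenchymal genes 6 rose, 4 fell and 9 were not called, or 7 and 5 adjusted over the list alone (median 0.20, 0.275).

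Of the signalling lists, immediate early genes were lower in the libraries labelled PHGDH-overexpressing: EGR1 (-1.25), IER3 (-0.64) and IER2 (-0.57) fell, with 1 higher, 8 lower and 6 not called, or 11 lower adjusted over the list alone (median -0.34, adjusted p of 0.00723, estimated correlation 0.343). The ATF4 list was higher, with the stress genes DDIT4 (1.61), NUPR1 (2.31) and TRIB3 (0.95) up; of 31 genes 14 rose, 4 fell and 13 were not called (median 0.12, adjusted p of 0.00997, estimated correlation 0.343). None of the 10 lists called in MDA-MB-231 held its call with an estimated correlation. Where no count adjusted over the list alone is given for these libraries, it equals that over all genes.

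The hexosamine and sialic acid list was not called in MDA-MB-231 (9 rose, or 10 adjusted over the list alone, 6 fell, 12 not called, median 0.13, adjusted p of 0.671). GFPT2 (0.47), GNE (0.31), ST6GAL1 (0.48) and ST6GALNAC5 (2.57) rose and UAP1 (-0.83) and ST3GAL6 (-0.80) fell; GFPT1 (-0.04), NANS (0.14), CMAS (0.13) and ST3GAL1 (0.04) were not called. Of 23 G2/M genes 11 rose, 2 fell and 10 were not called (median 0.10, 0.0911), with KIF23 (0.55), CCNB1 (0.35) and UBE2C (0.36) higher; without control replicate 1 the list was called (0.0337). MKI67 was not called (0.08, adjusted p = 0.402), but was called higher without control replicate 1 (adjusted p = 0.0129, edgeR). Of 22 S phase genes 11 rose, 4 fell and 7 were not called (median 0.13, 0.213), with MCM7 (0.45), MCM5 (0.31) and E2F1 (0.30). Of 16 nucleotide synthesis genes 4 rose, 3 fell, or 4 adjusted over the list alone, and 9 were not called (median -0.02, 0.993); IMPDH2 (0.30) and ATIC (0.28) rose and PPAT fell (-0.36). Of 18 unfolded protein genes 9 rose, or 10 adjusted over the list alone, and 3 fell (median 0.13, 0.171), with PDIA4 (0.52), XBP1 (0.50) and CANX (0.35) higher. Heat shock genes had 2 higher and 4 lower, or 3 and 5 adjusted over the list alone (median -0.05, mean 0.02, direction up, 0.909), with HSPB1 higher (0.79) and HSP90AA1 (-0.33) and HSPA1B (-0.23) lower.

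Secreted and immune lists were not called in MDA-MB-231 either. Of 16 hypoxia genes 4 rose, 7 fell and 5 were not called (median -0.08, adjusted p of 0.517), with VEGFA lower (-0.90) and BHLHE40 (1.06) and EGLN3 (1.09) higher. Of 15 inflammatory genes 4 rose, 4 fell and 7 were not called (median -0.19, 0.993): the chemokine CXCL1 fell (-3.80, from 2.57 to 0.186 CPM) and CSF1 (0.83) and NFKBIA (0.49) rose. Of 23 interferon genes 10 rose, or 12 adjusted over the list alone, and 2 fell (median 0.17, 0.108), with OASL (0.93) and XAF1 (1.08) higher and DDX58 lower (-0.57). Of 13 antigen presentation genes 3 rose, 4 fell and 6 were not called (median -0.04, 0.737), with CD74 higher (0.48) and CD274 (-0.75) and TAP2 (-0.38) lower. Of 14 p53 targets 4 rose, 5 fell and 5 were not called (median -0.01, 0.815), with PHLDA3 higher (1.01) and ZMAT3 (-0.68) and PLK2 (-0.50) lower. Of 18 YAP and TGF-beta targets 4 rose, 10 fell and 4 were not called (median -0.38, 0.0933), with CTGF (-1.24) and CYR61 (-0.88) lower and ID1 higher (1.30); without control replicate 1 this list was called (0.0337).

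Vascular and stromal marker lists in MDA-MB-231 were likewise not called. Of 13 endothelial markers 5 rose, or 6 adjusted over the list alone, 3 fell and 5 were not called (median 0.27, mean -0.15, direction up, adjusted p of 0.485). EGFL7 (1.04) and PTPRB (1.58) rose and TIE1 fell from 81 counts to 1, a ratio of 0.0129 with a counting interval of 0.000322 to 0.0738. Of 16 Notch and angiogenesis genes 4 rose, or 5 adjusted over the list alone, 7 fell and 5 were not called (median -0.18, 0.108). JAG2 rose (1.42), VEGFC fell (-0.63) and the chemokine receptor CXCR4 fell from 896 counts to 1, a ratio of 0.00116 with a counting interval of 2.94e-05 to 0.0065. Of 5 fibroblast markers 3 rose, 1 fell and 1 was not called (median 0.57, 0.275), with COL6A1 (0.57) and PDGFRB (0.84) higher and COL6A3 lower (-0.49). Of 6 leukocyte markers CSF1R (1.12) and LAPTM5 (0.47) rose, 0 fell and 4 were not called (median 0.11, 0.317).

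Of 17663 genes tested in MDA-MB-231, 3816 were higher and 4048 lower in the libraries labelled PHGDH-overexpressing, 44.5% of those tested, and 540 and 482 of them changed 2-fold or more. With library totals the counts were 3053 and 4900, a higher share of 38.4% against 48.5%. The coefficient of variation was 6.32%, and in simulated libraries 26% of genes with a log2 change of 0.263 and 96% with 0.585 were recovered. The next rankings hold among called genes with a mean of at least 10 CPM and no overlap between groups. The largest falls there were in the nerve growth factor receptor NGFR (2866 counts to 0, at least 916-fold lower), the lymphangiogenic CCBE1 (1672 to 0, at least 535-fold lower), ZNF521 (-6.08), the activin subunit INHBB (-4.98), the cystatins CST1 (-4.53) and CST4 (-3.17), the collagenase MMP1 (-4.40, from 115 to 5.45 CPM), the cadherin CDH11 (-4.25), PDE1C (-3.63) and PAPPA (-3.32). Under the same limits the largest rises were in the cancer-testis gene MAGEC2 (4.40), the laminin LAMA4 (2.37), KCNAB2 (2.34), CDK15 (2.33), the oxidase NOX5 (2.33), the keratin KRT81 (2.24), CA12 (2.21), ALDH3A1 (2.19) and MAGED4B (2.18) and MAGED4 (2.13), which are near-identical copies whose reads cannot be assigned with certainty. In all, 33 genes were at 3 counts or fewer over one group and at 1 CPM or more in the other. NGFR, CCBE1, TIE1 and CXCR4 were among them, and 30 of the 33 were present in the controls only. Human genes were not placed on chromosomes, so shifts like those between the knockdown arms were not looked for. A clonal or copy number difference between the MDA-MB-231 groups was therefore not tested.

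Genes that moved in the knockdown did not move on balance in the libraries labelled PHGDH-overexpressing. The 3034 matched genes higher in shPHGDH had a median of -0.03 there, with 758 higher and 895 lower and a camera p of 0.475 (0.376 with the estimated correlation). The 2832 matched genes lower in shPHGDH had a median of -0.02, with 677 higher and 786 lower and a camera p of 0.733 (estimated correlation 0.619). Across 9513 matched genes, which are not independent replicates, the Spearman correlation of the log2 fold changes was -0.00. Of 3116 genes called in both experiments, where 3026 would be called in both by independent lists, 50.4% went opposite ways (odds ratio 0.983; Fisher's exact test across genes, two-sided, p = 0.829). Read by the PHGDH level both experiments compare less PHGDH with more, and by the labels they are opposite; the experiments differ in species and line as well.

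Co-culture with Bend3 was measured with 1 library per line and condition, so the ratios carry counting intervals and no p-values. Phgdh was 3.06-fold lower in co-cultured 4T1 than in monocultured 4T1 (65 counts to 21, ratio 0.327, 95% interval 0.19 to 0.541). It was 3.06-fold lower in co-cultured EMT6.5 as well (50 counts to 10, ratio 0.327, 0.148 to 0.652). Other serine pathway genes were lower in both lines, and by more in 4T1: Psat1 (ratios 0.338 in 4T1 and 0.743 in EMT6.5), Psph (0.253 and 0.568), Shmt2 (0.293 and 0.647) and Mthfd2 (0.163 and 0.466). Shmt1 was at 0.665 in 4T1 and at 0.949 in EMT6.5, where its interval (0.648 to 1.38) includes 1. The serine and one-carbon list lay at the 0.01 percentile of matched random lists in 4T1 (median log2 ratio -0.79) and at the 4.83 percentile in EMT6.5 (-0.26).

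Stress and YAP target genes were among those furthest below monoculture in both co-cultured lines, as single-library ratios. The YAP targets Ccn2, also called Ctgf (ratios 0.026 in 4T1 and 0.129 in EMT6.5), Ankrd1 (0.0508 and 0.159) and Amotl2 (0.0356 and 0.333) were lower, as were the stress genes Atf3 (0.067 and 0.038), Chac1 (0.165 and 0.113) and Trib3 (0.0743 and 0.665) and the damage response gene Gadd45a (0.0695 and 0.222). In EMT6.5 Atf3 went from 43 counts to 1 (interval 0.000941 to 0.223). The cytokines Csf1 (0.117 and 0.453) and Ccl2 (0.227 and 0.35) and the adhesion molecule Vcam1 (0.285 and 0.248) were lower too. The ATF4 list lay at percentile 0 in both lines (medians -1.97 and -0.57, with 27 and 6 of 32 genes at least 2-fold lower), as did the inflammatory list (-0.91 and -0.92) and the YAP and TGF-beta list (-1.53 and -0.84). These were the 3 lists in the lowest 2.5% of random lists in both lines, and 0 lists lay in the highest 2.5% in both. Over all lists, 21 of 52 positions lay in these tails. Random lists would put 2.6 there if list members were independent, which they are not. Among replicates of the other experiments, set against 1 shared replicate, 3 to 12 positions lay there. In those comparisons 0 to 4 lists lay in the same tail in both ratios. A shared replicate alone moves both ratios the same way, while each tumour line had its own monoculture. The replicates therefore cannot say whether 3 shared lists are more than unchanged cultures would give. Other large falls were the protease Ctsw (0.0043, 235 counts to 1, interval 0.000108 to 0.0242, and 0.045), the metalloprotease Adam12 (0.00541, 187 counts to 1, interval 0.000136 to 0.0305, and 0.367), the kinase Plk2 (0.0625 and 0.112), Cldn4 (0.385 and 0.0162) and the keratin Krt80 (0.0604 and 0.181).

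Among genes with a mean of at least 20 CPM and beyond the median share of Bend3 RNA, the largest shared rises were in genes of different kinds. The calcification inhibitor Mgp was higher (ratios 236 in 4T1 and 73.5 in EMT6.5), as were the collagens Col6a2 (14.3 and 1280, the latter from 2 counts to 1560 with an interval of 352 to 1.05e+04) and Col6a1 (7.01 and 388), Mmp3 (75.3 and 6.54, the latter from 1 count to 4 with an interval of 0.647 to 322), the cornified envelope gene Ppl (12.5 and 81.7) and the inhibitor Id2 (19 and 7.83). Itga1 (49.5 and 3.05), Trib2 (30.1 and 3.61), Slpi (35.9 and 2) and Notch1 (21.1 and 3.05) were higher too, Trib2 not beyond the 90th percentile of carried-over Bend3 RNA. Of 10508 genes, 1390 were 2-fold higher and 1275 lower in 4T1, and 498 and 725 in EMT6.5. In both lines 178 were higher, against 65.9 from independent lists, and 196 lower, against 88.0. Opposite ways went 113 genes higher in 4T1 and lower in EMT6.5, against 95.9 from independent lists, and 34 the other way, against 60.4. The log2 ratios of the lines correlated across genes at r 0.21 (Spearman 0.175). Of the 178 shared rises 163 lay beyond the median share of Bend3 RNA and 143 (80.3%) beyond its 90th percentile.

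**Figure D4:**
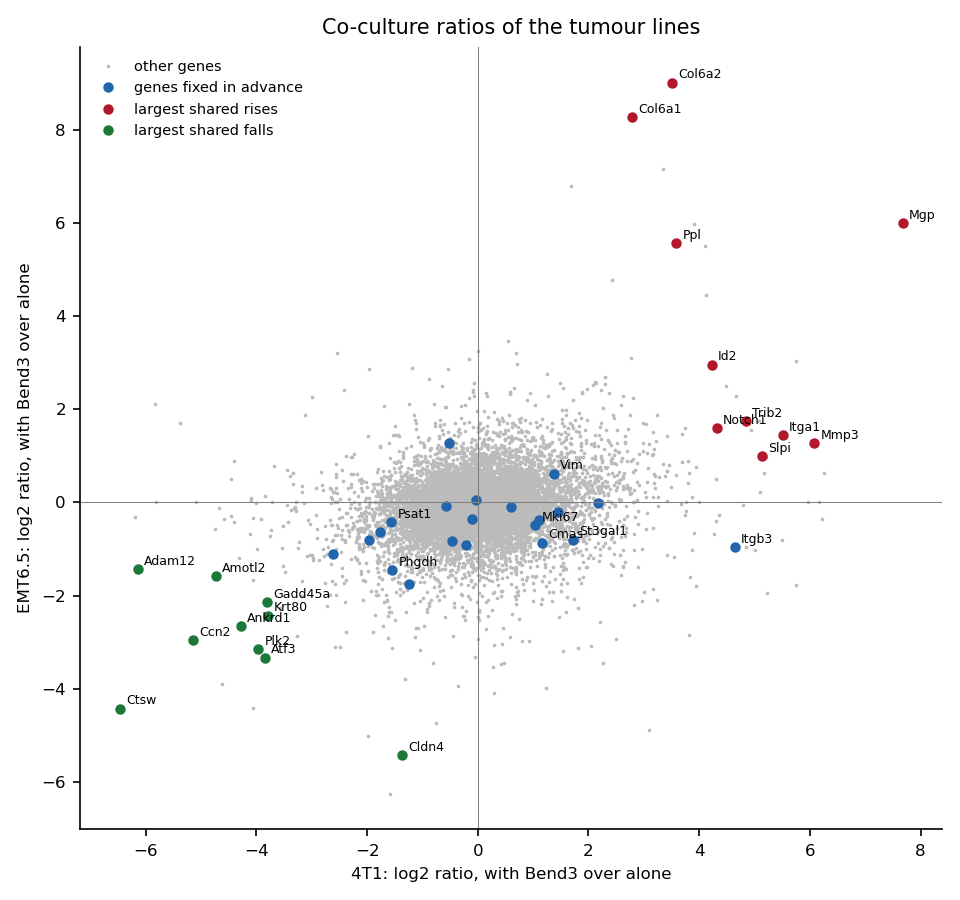
Log2 ratio of co-cultured to monocultured cells for each gene, in 4T1 (horizontal) and EMT6.5 (vertical), 1 library per condition, with core genes in blue and the largest shared rises and falls in red and green. Phgdh lies at -1.54 and -1.46, and 178 and 196 genes are at least 2-fold higher or lower in both.

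A fit of what both lines share, with the line as a block and 1 residual degree of freedom, called 35 of 12005 genes by edgeR, 20 higher and 15 lower, with 966 at an unadjusted p under 0.05; DESeq2 called 91, and edgeR without the block called 0. Mgp (log2 7.03, edgeR adjusted p = 0.000215), Id2 (3.64), Mmp3 (5.90), Ppl (4.68) and Col6a2 (7.30) were called higher. The Mmp3 call rests on 4T1, where it went from 14 counts to 1043. In EMT6.5 it went from 1 count to 4, with an interval (0.647 to 322) that includes 1. Ctsw (-5.20), Plk2 (-3.53), Atf3 (-3.97), Ccn2 (-3.93), Ankrd1 (-3.42), Chac1 (-2.82), Gadd45a (-2.96) and Krt80 (-3.08) were called lower. Phgdh was not called (-1.56, adjusted p = 0.643), nor were Psat1 (-0.95, 0.558), Psph (-1.35, 0.352), Mthfd2 (-1.81, 0.179) and Col6a1 (5.46, 0.0802).

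Several core genes went opposite ways in the co-cultured lines, in single libraries. Itgb3 went from 1 count to 64 in 4T1 (ratio 64.7, interval 11.2 to 2595), where Bend3 held 123 CPM, and from 1290 to 404 in EMT6.5 (ratio 0.512). Cmas (2.24 and 0.549), St3gal1 (3.32 and 0.574), Pfkl (2.16 and 0.764) and Mki67 (2.06 and 0.713) were higher in 4T1 and lower in EMT6.5, with intervals that exclude 1. Pfkm (2.79 and 0.865), Gfpt1 (1.51 and 0.936) and St6gal1 (4.58 and 0.993) were higher in 4T1, with intervals that include 1 in EMT6.5. Itgav (0.865 and 0.533), Itgb1 (0.726 and 0.56) and Gne (0.415 and 0.289) were lower in both and Vim (2.6 and 1.53) was higher in both. Nans (0.926 and 0.781) was lower in EMT6.5, and the intervals of Nans in 4T1 and of Pfkp in both lines (0.979 and 1.04) include 1. Cdh1 was at 0.699 in 4T1 and went from 1 count to 4 in EMT6.5 (interval 0.647 to 322). Gfpt2 was below the level needed for a ratio.

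By list, the medians in co-cultured 4T1 and EMT6.5 parted for cholesterol synthesis (0.63 at percentile 99.9 and -1.80 at 0, with 19 of 20 genes 2-fold lower in EMT6.5), G2/M (0.31 at 98.9 and -0.64 at 0), S phase (0.35 at 97.52 and -0.70 at 0) and integrins (0.43 at 97.1 and -0.56 at 0.09). The interferon response was at 0.68 (100) in EMT6.5 and at -0.06 (37.1) in 4T1, a difference that was not tested. Matrix remodelling (0.76 at 100), mesenchymal (0.56 at 99.4) and immediate early genes (0.69 at 99.9) were higher in 4T1 and at 0.03, -0.10 and 0.07 in EMT6.5 (70.5, 30.3 and 80.7). Endothelial markers were at 1.04 (99.9) and 0.32 (96.8), and at percentiles 63.9 and 11.9 once the share of Bend3 RNA was subtracted. Nucleotide synthesis was at -0.67 (0.96) and -0.27 (7.28), and hypoxia at 0.01 (62.8) and -0.42 (1.25).

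The other lists lay between these tails in both tumour lines. In 4T1 and EMT6.5 the medians were 0.06 and -0.05 for hexosamine and sialic acid (percentiles 71.1 and 48.3), 0.16 and -0.06 for epithelial genes (78.6 and 45.8), 0.16 and -0.30 for glycolysis (85.8 and 5.2) and 0.38 and 0.20 for antigen presentation (93.9 and 92.4). Notch and angiogenesis genes were at -0.49 and -0.15 (3.11 and 27.4), heat shock at 0.26 and 0.08 (87.4 and 76.5), p53 targets at -0.24 and 0.14 (19 and 89) and the respiratory chain at -0.42 and -0.10 (3.9 and 29.2). TCA cycle genes were at -0.35 and -0.20 (11.5 and 12.5), unfolded protein genes at 0.21 and -0.15 (93.5 and 19.8) and NRF2 targets at 0.07 and -0.08 (79.8 and 41.1). The 4 fibroblast markers (2.85 and 5.03) and 3 leukocyte markers (0.50 and -0.44) were too few for a percentile.

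**Figure D5:**
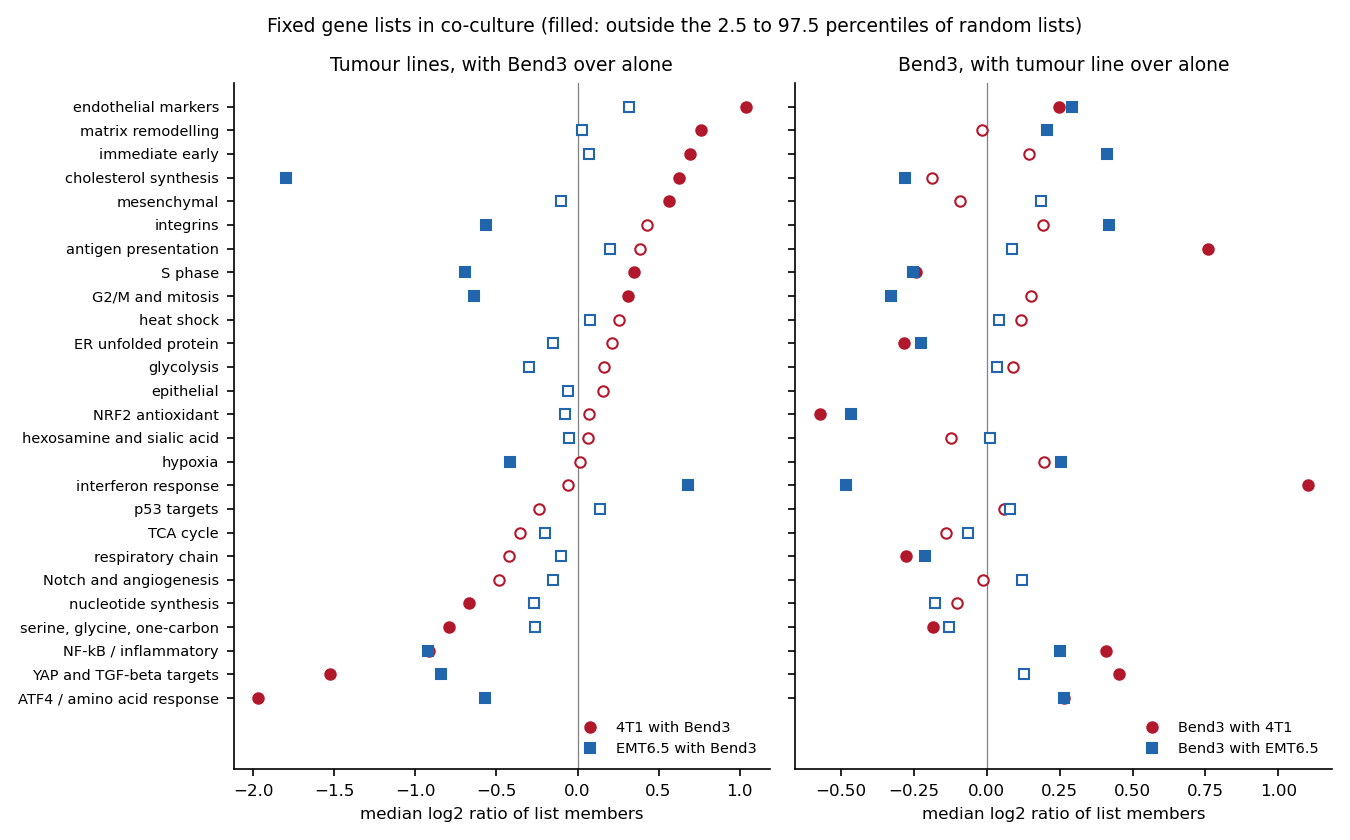
Median log2 ratio of co-culture to monoculture for each gene list with at least 5 members, in the tumour lines and in Bend3, with circles for the 4T1 pair and squares for the EMT6.5 pair and filled points in the lowest or highest 2.5% of matched random lists. The ATF4 list lies at -1.97 and -0.57 in the tumour lines and at 0.26 and 0.27 in Bend3.

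In Bend3, 3 lists lay in the highest 2.5% and 4 in the lowest 2.5% of random lists with both partners, again as single-library ratios. Both ratios share 1 monoculture, which alone moves them the same way; among replicates set against 1 shared replicate, 0 to 4 lists lay in the same tail. Endothelial genes were higher (Vwf at ratios 1.85 with 4T1 and 3.43 with EMT6.5, Plvap at 1.58 and 2.65, Sox18 at 1.94 and 2.13), and their list lay at percentile 100 with both (medians 0.25 and 0.29). The ATF4 list was higher (0.26 and 0.27, both at 100), the opposite of the tumour cells, with Atf3 (2.34 and 1.96), Nupr1 (2.29 and 1.69) and Ddit4 (1.98 and 1.88). The inflammatory list was higher too (0.41 at 99.9 and 0.25 at 97.6), with Birc3 (2.06 and 1.95), Ptgs2 (1.72 and 1.65) and Tnfaip3 (1.13, with an interval that includes 1, and 2.42). In the lowest 2.5% with both partners lay NRF2 targets (-0.57 and -0.46, both at 0; Nqo1 at 0.569 and 0.391, Fth1 at 0.551 and 0.517, Gclm at 0.636 and 0.46), the respiratory chain (-0.28 at 0.01 and -0.21 at 0.08; Ndufb10 at 0.664 and 0.563, Ndufa9 at 0.744 and 0.634, Atp5c1 at 0.647 and 0.746), unfolded protein genes (-0.28 at 0.07 and -0.22 at 0.53; Hyou1 at 0.51 and 0.544, Sdf2l1 at 0.65 and 0.583, Pdia6 at 0.592 and 0.677) and S phase genes (-0.24 at 0.75 and -0.25 at 0.69; Gins2 at 0.504 and 0.316, Mcm2 at 0.591 and 0.53, Mcm5 at 0.575 and 0.641).

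The core genes moved little in Bend3. Phgdh was at ratios 0.868 with 4T1 (95% interval 0.704 to 1.07) and 0.752 with EMT6.5 (0.605 to 0.935), from 37.5 CPM alone to 32.5 and 28.2. Psat1 (0.708 and 0.704), Shmt2 (0.821 and 0.915), Mthfd2 (1.09 and 1.1) and Psph (1.66 and 1.48) were within 2-fold, and so were Itgav (1.15 and 1.47), Itgb3 (1.14 and 1.34), Itgb1 (1.31 and 1.49), Gfpt1 (0.637 and 0.504), Nans (0.764 and 0.671), Cmas (0.952 and 0.946), Gne (0.869 and 1.12), St6gal1 (1.1 and 1.34), St3gal1 (1.6 and 1.54), Pfkl (1.17 and 1.32), Pfkm (1.16 and 1.14), Pfkp (1.29 and 1.17) and Vim (0.799 and 0.782). Gfpt2 was at 2.09 and 1.49, and Mki67 at 1.14 and 0.476. Shmt1 went from 3 counts to 22 with 4T1 (ratio 5.93, interval 1.78 to 31) and to 28 with EMT6.5 (7.53, 2.33 to 38.7). Its rise lay beyond the median share of carried-over tumour RNA, but not beyond the 90th percentile of that share in both libraries. Cdh1, an epithelial gene, went from 1 count to 27 with 4T1 (21.8, interval 3.6 to 894) and to 0 with EMT6.5; its 4.62 CPM with 4T1 did not lie beyond carried-over RNA, since the 4T1 partner held 451 CPM.

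Among the 10 largest rises shared by both Bend3 libraries beyond carried-over RNA, at a mean of at least 20 CPM, were Trp53i11 (ratios 3.94 and 4.91), the chemerin receptor Cmklr1 (2.6 and 5.91), Dapk2 (3.22 and 4.69), the orphan receptor Nr4a2 (2.45 and 6.18), Npnt (4.51 and 2.7), Pcdh17 (3.6 and 3.21), Cd200 (3.21 and 3.03), Pmepa1 (2.62 and 3.61) and Prss23 (3.25 and 2.86). Among the largest falls were the somatostatin receptor Sstr2 (0.153 and 0.187), Col6a3 (0.207 and 0.303), Nptx1 (0.231 and 0.395), Ddt (0.356 and 0.388), Id2 (0.37 and 0.445), Bhlhe41 (0.367 and 0.446), Gprin3 (0.337 and 0.496), Gstm1 (0.464 and 0.379) and Lrp8 (0.416 and 0.464). Of 9964 genes, 103 were 2-fold higher and 47 lower with both partners, with 251 and 170 with 4T1 and 207 and 175 with EMT6.5. Simulated with the spread of the shSCR libraries, the shared control alone gave a mean of 0.56 and 0.1 such genes and at most 6 and 1 in 100 simulations, and the correlation of the ratios was 0.60 against 0.548. That spread is close to counting error and not known to be between cultures, so the overlap that separate cultures of Bend3 would give was not measured. Of the 103 rises 82 lay beyond the median share of tumour RNA and 74 (71.8%) beyond its 90th percentile. A fit of both co-cultures against the monoculture, with 1 residual degree of freedom, called 0 of 12410 genes by edgeR, with 953 at an unadjusted p under 0.05, and 29 by DESeq2; edgeR with library totals called 60, and over genes with a mean of at least 5 CPM 104.

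Interferon genes in Bend3 parted by partner: the list lay at 1.10 (percentile 100) with 4T1 and at -0.48 (0) with EMT6.5. With 4T1 and with EMT6.5 the list medians were 0.76 and 0.09 for antigen presentation (percentiles 100 and 77.8), 0.15 and -0.33 for G2/M (95.4 and 0.01), 0.19 and 0.42 for integrins (95.6 and 100), 0.15 and 0.41 for immediate early genes (97 and 100) and 0.45 and 0.13 for YAP and TGF-beta targets (100 and 89.6). Serine and one-carbon genes were at -0.18 and -0.13 (1.93 and 7.02), hypoxia at 0.20 and 0.26 (94.6 and 98.5), cholesterol synthesis at -0.19 and -0.28 (6.11 and 1.7) and matrix remodelling at -0.01 and 0.21 (48.9 and 98.6, the latter 81.7 with tumour RNA subtracted). Between the tails with both partners were hexosamine and sialic acid (-0.12 and 0.01, 12.8 and 55.9), mesenchymal genes (-0.09 and 0.19, 20.3 and 95.4), glycolysis (0.09 and 0.03, 80.9 and 64.2), nucleotide synthesis (-0.10 and -0.18, 17.1 and 5.17), Notch and angiogenesis (-0.01 and 0.12, 48.1 and 90.1), heat shock (0.12 and 0.04, 78.1 and 64.1), p53 targets (0.06 and 0.08, 74.2 and 83.2) and the TCA cycle (-0.14 and -0.06, 7.22 and 24.4). The epithelial (2 genes, 4.30 and 1.66), fibroblast (1 gene, -2.23 and -1.70) and leukocyte lists (1 gene, -0.52 and -0.87) were too few for a percentile. Of 50 positions, 25 lay in the tails, against 3 to 12 among replicates, which came from other experiments and deeper libraries; this does not say which single lists moved.

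RNA of the partner made up a small share of each sorted library. Genes abundant in the partner and near absent in the host gave a median share of 1.29% Bend3 RNA in co-cultured 4T1 (103 genes, 10th to 90th percentile 0.0823% to 5.2%) and 0.478% in co-cultured EMT6.5 (91 genes, -0.149% to 2.73%). In Bend3 it was 1.69% with 4T1 (96 genes, 0.434% to 3.28%) and 1.24% with EMT6.5 (117 genes, 0.307% to 2.89%). With a stricter choice of genes the share was 0.732% in 4T1 and 0.914% in EMT6.5.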

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

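The tests of the PHGDH level in MDA-MB-231, of depth in the knockdown arms, of neighbouring genes in the co-cultured 4T1 cells and of the changes shared by the co-cultured tumour lines were chosen only after these results were seen; the window test of the knockdown arms was written before.

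PHGDH was lower in each MDA-MB-231 library labelled PHGDH-overexpressing than in each control, the opposite of the label. Scaling or depth is argued against, since the log2 fold change was -1.67 with library totals. Exchanged column names cannot be told apart from a true fall: the lowest control was 2.59 times the highest library labelled PHGDH-overexpressing, which an exchange would give and which a fall of endogenous PHGDH would give as well. A candidate explanation is also a cDNA whose reads the counting misses. Enzyme made from it would be predicted to lower the amino acid response; the ATF4 list was higher instead (camera adjusted p of 0.00997), but with the estimated correlation it was at 0.343, which keeps this open.

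The shPHGDH and shSCR cells differed by whole chromosomes and by 26 genes that were near 0 counts in one arm only. A copy number or clonal difference between the 2 transduced lines may explain part of this: the SD of the window medians was 3.10 times the highest shuffle. Neighbouring genes that move together in any 4T1 comparison stay open: the ratio was 1.08 in co-cultured against monocultured 4T1, where single libraries gave shuffles up to 0.158 and a window SD of 0.170, and the chromosome medians ran from -0.20 to 0.09, with chromosome 14 at -0.09 against 0.51 in the knockdown, so its shift was not seen there. Depth is argued against as the source of the switched genes, since the summed counts of the shSCR arm were 1.02 times those of the shPHGDH arm. Which of the other changes came from the fall of Phgdh and which from such a difference was not separable here, since the labels name 1 shRNA against PHGDH and no other 4T1 line with it.

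The co-cultured tumour lines shared 178 rises and 196 falls. Bend3 RNA is argued against as the source of most rises, since 80.3% of them lay beyond the 90th percentile share of that RNA in both lines. A 4T1 monoculture library out of place is argued against as the whole source, since EMT6.5, which has its own monoculture, shared 2.70 times the rises that independent lists would. Stress of sorting cannot be told apart from co-culture, since only co-cultured cells are said to have been sorted. The immediate early list lay at the 99.9 percentile in 4T1 and at the 80.7 percentile in EMT6.5. An effect of co-culture itself stays open as a hypothesis.

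Effects in 4T1 and EMT6.5 co-cultures went opposite ways for 5 core genes, each an untested difference between single libraries on the log2 scale. Itgb3 was at 4.64 in 4T1 and -0.96 in EMT6.5, a difference of 5.61. Cmas was at 1.16 and -0.86, 2.02 apart. St3gal1 was at 1.72 and -0.80, 2.52 apart. Pfkl was at 1.10 and -0.39, 1.49 apart. Mki67 was at 1.04 and -0.49, 1.53 apart.

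The same untested contrast was seen for whole lists. The G2/M list was at 0.31 in 4T1 and -0.64 in EMT6.5, a difference of 0.95, and the S phase list at 0.35 and -0.70, a difference of 1.04. Cholesterol synthesis was at 0.63 and -1.80, a difference of 2.43. In Bend3 the interferon list was at 1.10 with 4T1 and -0.48 with EMT6.5, a difference of 1.58. None of these differences was tested, since each condition has 1 library.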

How the results depend on the processing

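The count without the shifted chromosomes was the test chosen only after the result was seen; the other alternatives were set beforehand. None of the main results and called named genes compared under the alternatives changed direction. For named genes not called as reported, a change of sign was not counted as a change. Outside them, 9 called genes of the knockdown changed sign with lane in the model, and so did the tested direction of the serine, G2/M and NRF2 lists, which were not called either way. The balance of calls turned as well, from 3484 higher and 3421 lower to 3027 and 4023 with library totals in the knockdown, and from 3816 and 4048 to 3370 and 3338 with DESeq2 in MDA-MB-231. Where a count moved the cause was not tested, unless stated.

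With a 2-fold limit, which counts fewer genes by construction, 333 and 220 genes were higher and lower after knockdown and 540 and 482 in MDA-MB-231. Camera with an estimated correlation called 0 lists in the knockdown and 0 in MDA-MB-231, and fry, which asks another question, called 18 and 22. The remaining counts of genes stayed within 1.5 times the reported ones under DESeq2, limma voom, RLE, library totals, the filters, an adjusted p under 0.01 and lane. Without the genes of the shifted chromosomes 2507 and 2477 genes and 11 lists were called. Phgdh stayed between -3.04 and -2.96 in the knockdown and PHGDH between -1.69 and -1.48 in MDA-MB-231.

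Leaving out each replicate gave 3248 to 3405 genes higher and 3040 to 3257 lower after knockdown, 9 to 11 lists, and Phgdh at -3.03 to -2.97. In MDA-MB-231 it gave 3245 to 3925 higher, 3352 to 4183 lower, 9 to 12 lists, and PHGDH at -1.69 to -1.48. With a replicate block 3356 and 3229 genes were called after knockdown and 3758 and 4003 in MDA-MB-231, with 11 and 10 lists, and the matched knockdown genes had medians of -0.03 and -0.02. The residuals of same-numbered libraries, taken as if paired, correlated at -0.00, -0.03 and -0.05 in the knockdown and at 0.04, 0.01 and -0.02 in MDA-MB-231, so the numbers gave no sign of pairs.

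Of 1100 values for 110 named genes in the knockdown 1078 kept their side of the threshold, 18 lost a call (Shmt1, Shmt2, Lyz2 and Cd14) and 4 gained one (Pfkl and Mki67). Of 1062 values for 118 named genes in MDA-MB-231 1057 kept theirs, 3 lost a call (PSAT1) and 2 gained one (ITGB3 and MKI67). The matched knockdown genes were not called in MDA-MB-231 in any alternative (p of 0.216 to 0.768 for the higher set and 0.0776 to 0.752 for the lower set).

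With a floor of 1 CPM, 388 genes were higher and 330 lower in both tumour lines and 360 and 192 in both Bend3 libraries; with 20 CPM these were 86, 108, 27 and 11, and at 4-fold 25, 18, 9 and 1. A floor or limit changes the genes counted by construction. The effect common to the tumour lines was called for 91 genes with DESeq2 and for 0 with edgeR without the replicate block of the line, against 35. In Bend3 it was 29 with DESeq2, 60 with library totals and 104 with a mean of at least 5 CPM, against 0 as reported. List positions in the tails numbered 45 to 46, against 46.

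The share of partner RNA under a stricter choice of genes was 0.732% in 4T1 (12 genes), 0.914% in EMT6.5 (5 genes) and 0.883% in Bend3 with EMT6.5 (18 genes). Taken against the monocultured partner it was 1.22% in Bend3 with 4T1 and 0.993% in Bend3 with EMT6.5. Depth limits the co-culture, as does having 1 library per condition: at 4.27 to 7.67 M counts per library, the interval of Phgdh in EMT6.5, from 50 counts to 10, runs from 0.148 to 0.652.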

Other observations

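The tests of the knockdown genes in the co-cultured 4T1 cells were chosen only after the result was seen, and the test in EMT6.5 before; genes named in the next 2 paragraphs were chosen after their values were seen.

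Genes of the YAP and TGF-beta list went both ways in the co-cultured tumour lines. Ccn2 and Ankrd1 were lower in both lines. The differentiation inhibitors were higher in both, Id1 at log2 ratios of 2.29 in 4T1 and 2.55 in EMT6.5, Id2 at 4.22 and 2.96, and Id3 at 2.45 and 1.81. In the fit of both lines Id1 (2.48), Id3 (2.18), Fos (2.43) and Egr3 (4.16) were called higher, and the vessel factors Edn1 (-4.56) and Pdgfb (-2.80) lower. The fall of sterol genes in co-cultured EMT6.5 covered Cyp51 (-2.88), Msmo1 (-2.70), Insig1 (-2.56) and Hmgcs1 (-2.17), while in 4T1 Dhcr7 (3.01) and Insig1 (2.21) were higher and Msmo1 (-1.07) lower.

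Interferon genes differed between single libraries, which was not tested. In co-cultured EMT6.5 Isg15 (3.08), Ifit1 (2.88) and Rsad2 (2.41) were higher, and in 4T1 Rsad2 (-2.42) and Cxcl10 (-3.85) lower, though Irf7 was higher in both (2.14 in 4T1 and 2.56 in EMT6.5). In Bend3, by partner, Oas2 was at 1.80 with 4T1 and -2.77 with EMT6.5, Ifi44 at 1.83 and -0.39 and Isg15 at 1.53 and -0.59, and the antigen presenting H2-K1 was at 1.93 and 0.31.

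Phgdh was at 168 CPM in the shSCR 4T1 cells and at 15 CPM in the monocultured 4T1 cells of the co-culture set. The tables were counted separately, and the difference was not tested.

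If the lower Phgdh of co-cultured tumour cells moved the genes of the knockdown, genes 2-fold lower after knockdown would be predicted to lie low there. They lay at the 99.7 percentile of matched random lists in co-cultured 4T1 (88 genes, median 0.42) and at the 72.4 percentile in EMT6.5 (median 0.00), so this prediction was not met. The knockdown changes were not separable from a copy number or clonal difference, so this does not decide whether the lower Phgdh acted there. The 199 genes 2-fold higher after knockdown lay at the 100 percentile in both, with medians of 0.99 and 0.18, so the match was in one direction only.

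The 6 libraries of each replicated experiment can be parted into 3 and 3 in 10 ways, too few for a share under 0.05, since the smallest is 0.1. Counting the real split itself, 1 of the 10 gave as many called genes after knockdown (6905 in the real split, highest other 0) and 1 of 10 as many lists (11, highest other 4). In MDA-MB-231 it was 1 of 10, again the real one, for genes (7864, highest other 0) and for lists (10, highest other 7). For the matched knockdown genes in MDA-MB-231, 5 of 10 splits with the real one included gave a camera p as small for the higher set (0.475, lowest other 0.204) and 4 of 10 for the lower set (0.733, lowest other 0.305).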
